A study of Homo sapiens with 48 samples.

How the data were processed

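Gene expression was measured on Illumina bead arrays in 2 human cell lines, Huh7 (a hepatoma line) and THP1 (a monocytic leukaemia line), after transfection of 1 of 3 siRNAs. INTG is the siRNA against the transcript between C5 and TRAF1, and NC1 and NC2 are negative control siRNAs. Per the labels' protocols, 300000 cells per well received 50 pmol siRNA and were collected after 2 days. Each of 4 experiments per line used its own culture passage and 2 wells per siRNA, which gave 48 arrays, 8 per group. Experiments 1 and 2 are the discovery phase and experiments 3 and 4 the validation phase. Each phase of a line filled 1 slide of 12 arrays, so slide and phase cannot be told apart. Every slide held all 3 siRNAs of its line, but the array positions were tied to the siRNA. On the discovery slides NC1 filled positions A to D, NC2 E to H and INTG I to L. On the validation slides each experiment ran in the order NC1, NC2, INTG. An effect of position or order was not separated from that of the siRNA.

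Per the file headers, the deposited intensity values are mean bead signals per probe with a detection p-value against the array's negative controls. The values show no background subtraction and no normalization. A second table holds the authors' processed intensity on a linear scale. Its column medians are 1.09 throughout the Huh7 validation slide and -3.81 throughout the THP1 validation slide, and run from 1.52 to 1.61 and from -4.25 to -4.18 on the Huh7 and THP1 discovery slides. The values point to background subtraction and a normalization slide by slide that left small differences on the discovery slides. The steps themselves are not given in the sources used here. The submitters' processing notes name lumi and limma with no version.

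The table lists 48803 probes, of which 8 with blank values were left out. Through the platform annotation 28098 probes carry 1 gene symbol, 13 several and 20692 none, and no gene was named from a probe with several symbols. Scanner signals were background corrected by normexp with the detection p-values (offset 16), quantile normalized over all 48 arrays and put on the log2 scale with neqc in limma 3.58.1 under R 4.3.3. A probe was tested in a line where its detection p-value was under 0.01 on at least 8 of the 24 arrays. The 2 wells of an experiment were averaged, so that n is 4 experiments per group. Each line was fitted with limma (lmFit and eBayes), with siRNA and experiment as terms and 6 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The contrasts were INTG minus the mean of NC1 and NC2, INTG minus each control, and NC2 minus NC1. A joint fit gave the difference of the INTG effect between lines. The experiment was the block because same-numbered arrays share a culture passage per the series' design text. Deviations from the group means correlated at 0.458 to 0.918 within every experiment. A shift between slides alone would also give such correlations, so they do not favour the experiment over the slide as block. The number of arrays limits the precision.

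Gene lists, 40 in all, were fixed before the data were examined. Those with at least 5 measured genes, 35 in Huh7 and 33 in THP1, were tested with camera (preset correlation 0.01, 1 probe per gene, the brightest), with camera under an estimated correlation and with fry beside it. Named genes follow a rule also fixed then: measured neighbours of the target, the 12 highest and 12 lowest genes per line among those past the threshold with INTG on 1 side of both controls in all 4 experiments, up to 4 members of each called list, and up to 5 genes per direction in the other comparisons. For several probes of a gene, the probe with the smallest p was taken and the others were compared with it. A probe not detected on any array of a group has only a bound there, set by the dimmest detected probes.

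The fits were tested on simulated data with the residual spread of each probe in the real fits. The noise was drawn independently for each probe and well. Errors shared by probes, such as those of a dim array, were thus not covered. In Huh7, with 200 of 13878 probes changed, 90% of falls and 96% of rises of 0.50 on the log2 scale were recovered, and all of those of 1.00. In THP1 (13524 probes) the shares were 44% and 48% at 0.50, and 84% and 86% at 1.00. For the difference between lines (11542 probes) they were 35.9% and 47.4% at 0.50. Unchanged probes made up 3.5%, 7.09% and 7.76% of the simulated calls in these fits.

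Alternatives fixed before the data were examined covered the block, the duplicate wells, pooled controls, background correction, normalization, the authors' values, the detection filter, array weights, each phase alone and each experiment left out. How to log the authors' values was not fixed then: values under 0 were set to 0 and the offset of 16 was added, and a floor at 1 with no offset was run as well. Chosen after seeing the data, besides that floor, were fits that leave out the 2 dim INTG arrays of THP1 experiment 4 or that use array brightness as a covariate. No genome build is named in the files, so gene order was taken from the RefSeq table of GRCh38.p14 and no coordinates are given. A planned test for matches of the siRNA in transcripts needs sequences not used here.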

Results

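The arrays compared an siRNA against a transcript between C5 and TRAF1 on chromosome 9 (target sequence AACTACGTGAAGAGGCCTCTG) with 2 negative control siRNAs, in 4 experiments per line. Mean signals per array lay between 240.6 and 396.8 in Huh7. In THP1 they lay between 122.2 and 478.2. Duplicate wells correlated at 0.985 or more in Huh7 and 0.935 or more in THP1. Albumin (ALB) was detected on all 24 Huh7 arrays and on 1 THP1 array, and the myeloid factor SPI1 on 0 Huh7 and 24 THP1 arrays. The monocyte markers LYZ and CD14 were detected in both lines, and LYZ had a higher mean in Huh7 (10.26 against 7.51 on the log2 scale).

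**Figure D1:**
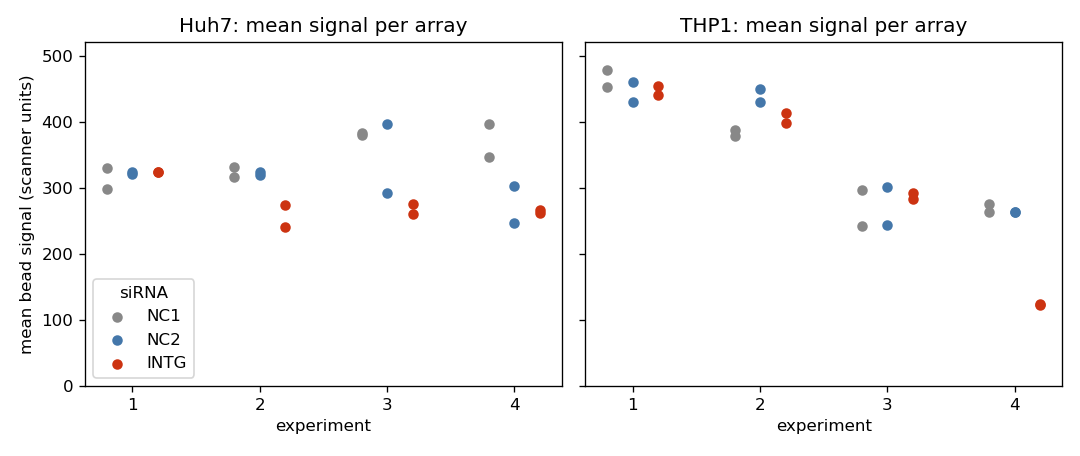
Mean bead signal of each array (scanner units) by experiment, for Huh7 (left) and THP1 (right), coloured by siRNA. The INTG arrays of THP1 experiment 4 average 122.9, against 269.5 and 262.8 for the controls of that experiment.

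Array brightness differed between siRNAs in part of the experiments. The ratio of INTG to control signal in Huh7 was 1.02 in experiment 1 and 0.798, 0.739 and 0.819 in experiments 2 to 4. In experiment 4 of Huh7 the NC2 arrays (mean 274.8) were close to INTG (264.7), and NC1 was brighter (371.8). In THP1 the ratio was 0.983, 0.986 and 1.06 in experiments 1 to 3 and 0.462 in experiment 4. Both INTG arrays of that experiment had fewer detected probes (mean 8685.5) than its NC1 (11292.5) and NC2 arrays (11721.5).

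The first question was what happened to the genes beside the target. C5, a complement component, did not pass the test in either line. Its log2 fold change against the mean of the controls was 0.12 in Huh7 (SE 0.069, 95% interval -0.04 to 0.27, limma, Benjamini-Hochberg adjusted p = 0.256, n = 4). In THP1 it was 0.04 (SE 0.063, interval -0.10 to 0.19, adjusted p = 0.72). TRAF1, an adaptor of TNF receptors, was detected on 0 of 24 arrays in each line with either of its 2 probes, so no fold is given. PHF19, a Polycomb-associated protein encoded beside TRAF1, fell in Huh7 with 2 of its 3 probes, by 0.84 (SE 0.083, adjusted p = 6.61e-05) and 0.77 (SE 0.08, adjusted p = 9.24e-05). The other PHF19 probe (probe 1 in the plot of genes around the target), annotated to another transcript, read -0.10 (SE 0.121, adjusted p = 0.585).

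FBXW2 fell by 0.29 in Huh7 (adjusted p = 0.0206), and STOM rose by 0.45 with 1 probe (adjusted p = 0.00282) while its other probe read 0.06 (adjusted p = 0.538). GSN, CNTRL and PSMD5 did not pass. In Huh7, 2 of the 7 neighbours counted with 1 probe each passed, both down, and the same 2 did so adjusted over the list alone. In THP1, 0 of 7 passed by either count. There PHF19 read -0.04, -0.12 and -0.26 with probes 1 to 3, and probe 3, which is not the one counted, lay below the controls in all 4 experiments (SE 0.068, interval -0.42 to -0.10, adjusted p = 0.298, and 0.0502 over the list alone). Camera did not call the list in either line (adjusted p = 0.446 and 0.187). The targeted transcript has no named probe here, and probes without a gene symbol were not searched for it, so its own level was not read. The only RefSeq gene between TRAF1 and C5 is the noncoding C5-OT1.

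**Figure D2:**
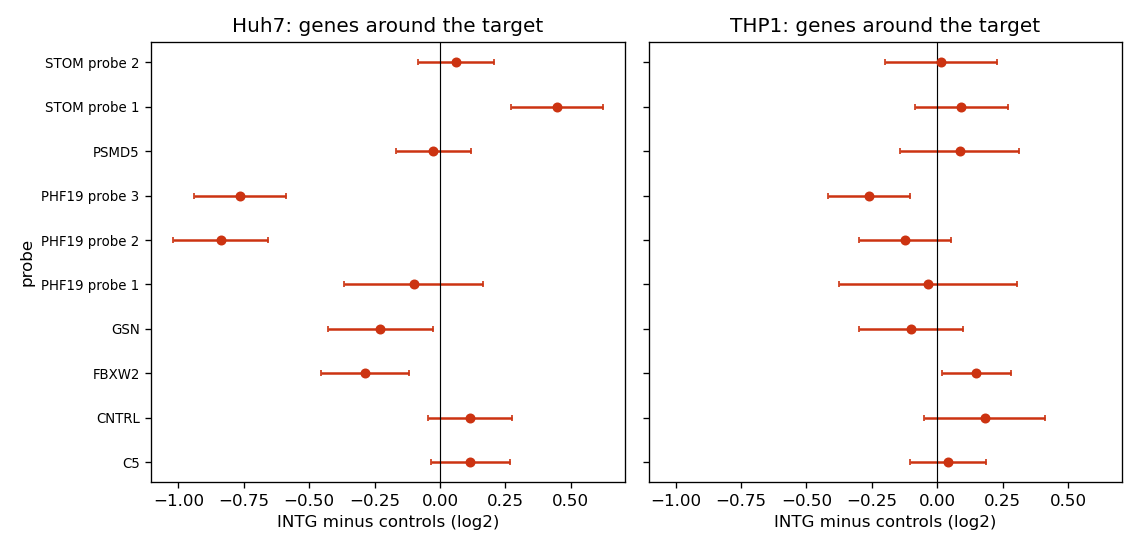
INTG minus controls (log2, with 95% intervals, n = 4 experiments) for each tested probe of genes around the target in Huh7 (left) and THP1 (right). In Huh7 PHF19 probes 2 and 3 lie at -0.84 and -0.77, probe 1 at -0.10 and C5 at 0.12.

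In Huh7 the INTG siRNA was followed by many changes on both sides. The deepest falls were in PNKD (-2.04, SE 0.127), the translocon subunit SSR1 (-1.64, SE 0.127), the reductase CYB5R3 (-1.62, SE 0.117), the zinc transporter SLC39A1 (-1.54, SE 0.073) and NDRG3 (-1.49, SE 0.124). The kinase MAP2K3 (-1.43), CCDC32 (-1.41), PRICKLE4 (-1.40), the pentraxin NPTX2 (-1.39), the deubiquitinase YOD1 (-1.35) and TTPAL (-1.35) followed. AGAP3 was not detected on the INTG arrays with 1 probe, at least 1.86-fold lower, while its other probe read 0.12. NDRG3 was detected on 4 of 8 INTG arrays with the probe given, so the size of its fall is less certain. The second PNKD probe read -0.11, whereas second probes of CYB5R3 (-1.67) and NDRG3 (-1.48) were close to the first. The other MAP2K3 probes lay between -0.74 and -0.52.

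The largest rises were in the matrix proteoglycan VCAN (1.35, SE 0.074), the lysophosphatidic acid receptor LPAR1 (1.26, SE 0.114), the glycosyltransferase LFNG (1.21, SE 0.162) and osteopontin, SPP1 (1.18, SE 0.099). The other SPP1 probe read 1.32, above LPAR1 and LFNG. SPTSSB (1.11), the aldo-keto reductase AKR1C3 (1.11), TSPAN12 (1.09), HLA-DMB (1.05) and the ectonucleotidase NT5E (1.02) came next. TNFRSF11B, which encodes osteoprotegerin, rose by 1.01, the prostaglandin receptor PTGER4 by 1.00 and FAM43A by 0.94. By the rule that named them, all of these genes lay on 1 side of both controls in all 4 experiments. Their largest limma adjusted p was 0.00188 (Benjamini-Hochberg), that of AKR1C3. Control signals of some were near background: AKR1C3 was detected on 1 of 8 NC1 and 2 of 8 NC2 arrays, LPAR1 on 4 and 4, HLA-DMB on 4 and 5, and FAM43A on 5 and 4, so their folds are less certain.

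**Figure D3:**
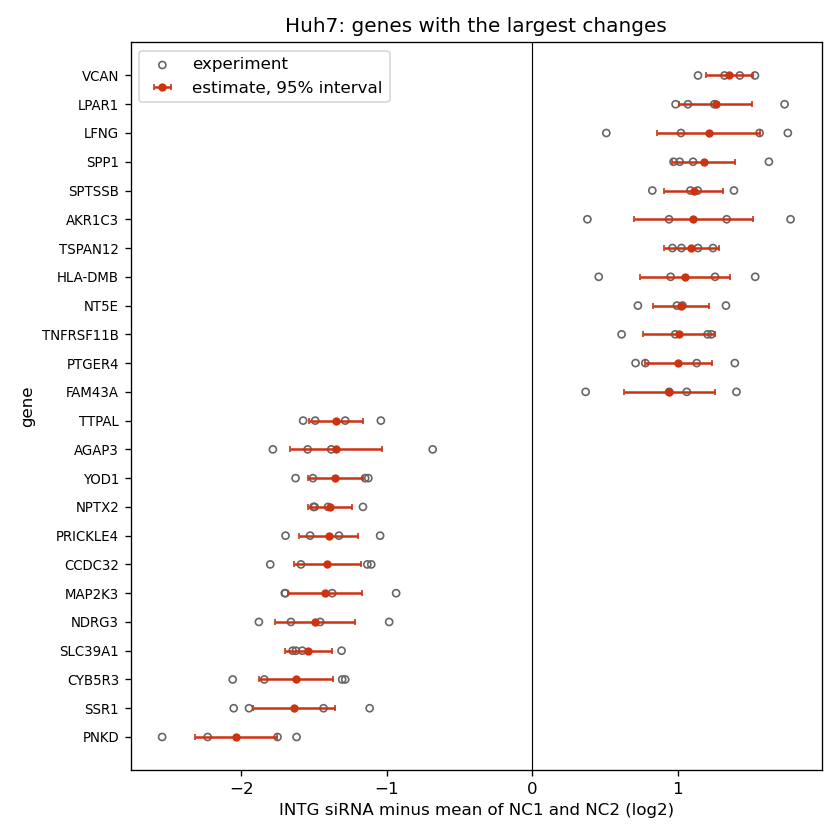
INTG minus the mean of NC1 and NC2 (log2) in Huh7 for the 12 highest and 12 lowest genes. Filled points give the estimate with its 95% interval and open circles the 4 experiments. VCAN is highest at 1.35 and PNKD lowest at -2.04, and AGAP3, not detected with INTG, is drawn at its fitted value.

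Of 13878 probes tested in Huh7, 1430 rose and 1659 fell, which is 1142 and 1301 genes (limma, Benjamini-Hochberg adjusted p under 0.05). Against both controls singly, 570 probes rose and 986 fell. The changes were mostly small: the median size among the 3089 calls was 0.36, with 14 rises and 59 falls beyond 1.00. Without the experiment as a block the 3089 became 333 and the 1556 against both controls 142, and with array brightness as a covariate, chosen after seeing the data, they became 532 and 206. With the slide as the only block they were 1132 and 469, and the 1556 became 2615 with wells as separate arrays. They were 2006 and 861 without experiment 1, 1989 and 817 without experiment 2, and 1766 and 715 without experiment 4.

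Members of several gene lists changed too. Of 9 measured metallothionein and zinc genes, 8 fell and 0 rose, among them the metal-binding proteins MT2A (-0.61), MT1M (-0.60), MT1X (-0.57) and MT1E (-0.53). MT1X also differed between the controls (NC2 minus NC1 -0.55, adjusted p = 0.0359). Of 21 genes of the unfolded protein response and ER chaperones, 9 fell and 1 rose. EDEM1 (-0.91), the chaperone calnexin (CANX, -0.71), SDF2L1 (-0.53) and HYOU1 (-0.43) fell, and DNAJB9 rose by 0.23.

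Of 19 acute phase and secreted liver proteins 7 fell, among them SAA4 (-1.07), the iron hormone hepcidin (HAMP, -0.68), haptoglobin (HP, -0.58) and hemopexin (HPX, -0.49), while A2M rose by 0.41 and ALB read 0.05 (adjusted p = 0.618). Of 15 lipoprotein and lipid transport genes 5 fell and 0 rose, among them APOC3 (-0.53), the cholesterol exporter ABCA1 (-0.33), APOB (-0.28) and APOC2 (-0.19). Adjusted over the list alone, the falls were 8, 10, 7 and 6 in the order of these lists.

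These 4 lists of 35 passed camera with a preset correlation, with Benjamini-Hochberg adjusted p = 0.000568 for metallothioneins, 0.000663 for the unfolded protein response, 0.0408 for acute phase proteins and 0.0408 for lipoproteins. None of them held with an estimated correlation: the adjusted p was 0.336, 0.336, 0.76 and 0.336 in that order. By fry, which asks whether a list's genes move to 1 side and not whether they differ from other genes, 14 lists were called in Huh7 and 1 in THP1. Other assignments of the siRNA labels within experiments gave at least 4 lists by camera in 8 of 81 cases, the real one included, and 2 lists were called without experiment 1 or without experiment 3. Of 12 housekeeping genes 0 changed.

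The 2 control siRNAs were compared as the background of the design. In Huh7 they differed at 66 probes, 39 higher and 27 lower with NC2. KLC1 (0.97), the cell cycle factor E2F2 (0.79), the defensin DEFB1 (0.77), the receptor kinase MET (0.77) and PIP4K2A (0.71) were higher with NC2. MET was detected on 1 of 8 NC1 and 4 of 8 NC2 arrays and DEFB1 on 4 and 8, so their differences are less certain. MPRIP (-1.18), the histone gene H2BC12 (-0.90), EIF5A2 (-0.84), FXR1 (-0.81) and DPH2 (-0.78) were lower. For FXR1 the INTG siRNA read 0.16 against NC1 and 0.97 against NC2, so most of its distance from the mean of the controls (0.57) lay in NC2. With 1 experiment left out the controls differed at 3 to 12 probes, 3 of them without experiment 1 or 4, 9 without experiment 3 and 12 without experiment 2. The 66 became 187 with no background correction, 164 with detection on all 24 arrays, 237 with array weights, 405 with wells as separate arrays, 24 with the authors' values at a floor of 1, 14 with the brightness covariate and 12 with the slide as the only block. Without the block, or on either slide alone, limma called 0. In THP1 limma called 0 probes between the controls, with 237 at an unadjusted p under 0.05. That is fewer than the 676 expected with no difference, so the 0 does not show that the controls agree. Between the controls camera called 1 list in Huh7, that of the histones, and 2 in THP1.

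The design repeated the discovery phase in a validation phase. The genes named first were picked among discovery calls with the same sign and an unadjusted limma p under 0.05 in validation. Their repeat thus follows from the choice. VCAN rose by 1.37 in discovery and 1.33 in validation, SPP1 by 1.15 and 1.49 with the probe named for this comparison, and LPAR1 by 1.03 and 1.49. PNKD (-1.92 and -2.15), SLC39A1 (-1.47 and -1.61), CYB5R3 (-1.41 and -1.93) and NPTX2 (-1.33 and -1.45) fell in both. Of 1217 discovery calls in Huh7, 1150 (94.5%) had the same sign in validation, and 860 of these had an unadjusted p under 0.05. The 860 became 528 with no detection filter, 489 with array weights, 436 with the authors' values, 170 without the block and 2004 with wells as separate arrays, and with the authors' values at a floor of 1 there were 0. Each setting made its own discovery calls, whose number was not kept, so these counts are not shares of the 1217. Validation alone gave 817 calls, of which 463 were also discovery calls of the same sign. Across probes, which are not independent replicates, the phases correlated at r = 0.646. The fit of the phase difference called 0 probes, with 1273 at an unadjusted p under 0.05.

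In THP1 few genes passed. CYB5R3 fell by 0.96 (SE 0.072, limma Benjamini-Hochberg adjusted p = 0.0119) and by 0.83 with its second probe, PNKD by 0.79 (SE 0.085, adjusted p = 0.0416), the iron-sulfur assembly gene ISCA1 by 0.57 (SE 0.06) and the adhesion protein vinculin (VCL) by 0.53 (SE 0.059). TEX19 rose by 0.81 (SE 0.088, adjusted p = 0.0416). Other probes of PNKD (-0.41), ISCA1 (-0.17) and VCL (-0.36 in discovery and -0.54 in validation) did not pass over the 4 experiments. These are the 6 probes past the threshold of 13524 tested, with 1612 at an unadjusted p under 0.05. Against both controls singly only 1 probe passed, a fall. Without the 2 dim INTG arrays of experiment 4 the 6 became 36, which added falls of SSR1 (-0.61), SLC39A1 (-0.53), the calcium-binding S100A8 (-0.75) and TOB1 (-0.65). No probe passed without the block or when experiment 1, 2 or 3 was left out, and 19 passed without experiment 4. The count was 18 with pooled controls, 30 with the brightness covariate, 36 with no background correction, 139 with detection on all 24 arrays, 259 with array weights and 547 with wells as separate arrays. With no detection filter it was 3, and with the authors' values at a floor of 1 it was 1.

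THP1 discovery alone gave 282 calls, 104 up and 178 down, and validation alone 0, with 900 probes at an unadjusted p under 0.05. Of the discovery calls 61 had the same sign and an unadjusted p under 0.05 in validation, 0 of them past the threshold when adjusted over the discovery calls. The 61 became 26 with array weights, 97 with detection on all 24 arrays, 103 with pooled controls, 110 with no background correction, 395 with wells as separate arrays, and 0 without the block or with the authors' values on either log scale. Discovery calls were again made anew in each setting, so these counts are not shares of the 282. The 61 include TEX19 (0.88 and 0.74), FXR1 (0.52 and 0.38), the immediate early gene FOS (0.51 and 0.41), the importin KPNA3 (-0.66 and -1.30) and the phospholipase PLCG2 (-0.67 and -0.73). KPNA3 read -0.75 in experiment 3 and -1.84 in experiment 4, with the dim arrays, and PLCG2 -0.42 and -1.05. Over the experiments without the dim arrays both fell, KPNA3 by 0.69 (adjusted p = 0.0336) and PLCG2 by 0.59 (adjusted p = 0.0346). The median of all tested probes in validation was -0.14. The phase difference itself gave 0 calls, with 1137 at an unadjusted p under 0.05. The cholesterol biosynthesis list was called upward by camera (adjusted p = 0.00138) with 0 of 22 members past the threshold, HMGCS1 at 0.25 and FDPS at 0.20. FDPS read 0.44 in experiment 4, that of the dim arrays, and 0.09 to 0.14 in the others. With an estimated correlation the adjusted p of the list was 0.425, and without the dim arrays 0 lists were called.

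The last comparison asked whether the lines responded differently. The effect differed at 300 of 11542 probes measured in both (limma interaction, Benjamini-Hochberg). Of these 278 had the smaller change in THP1 and 148 had opposite signs in the lines. Signs here are those of the estimates, whether or not the change passed in THP1. PTGER4 (difference 1.13, adjusted p = 0.000825), SPRY4 (1.10, adjusted p = 0.000825) and LFNG (1.72, adjusted p = 0.00437) were higher in Huh7 than in THP1 by this contrast. NT5E (1.18) and IVNS1ABP (1.24) were as well. PNKD (-1.25), MBNL3 (-1.24), AMMECR1 (-1.19), the nucleoporin SEH1L (-1.17) and SSR1 (-1.14) were lower in Huh7 by it. Other probes of PNKD (0.30, adjusted p = 0.503, with -0.11 in Huh7 and -0.41 in THP1), MBNL3 (-0.38, adjusted p = 0.25) and IVNS1ABP (1.19, adjusted p = 0.0987) did not pass, nor did 1 of the other 2 of SEH1L (-0.17, adjusted p = 0.311). Of these genes PNKD passed in THP1 over all probes, and SSR1 (-0.50 in THP1) passed when adjusted over the Huh7 calls or without the 2 dim arrays. In THP1 some signals were near background, with LFNG detected on 5 or 6 of 8 arrays per siRNA and SPRY4 on 1 to 4. Without the 2 dim arrays the count was 523, of which 237 had opposite signs, with LFNG at 1.45, NT5E at 0.93 and IVNS1ABP at 0.79. Leaving out 1 experiment of both lines gave 44, 63, 23 and 277 probes for experiments 1 to 4, and the fit without the block gave 1. The 300 became 58 with the slide as the only block, 508 with detection on all 24 arrays, 649 with array weights and 1347 with wells as separate arrays, and 46 and 0 on the discovery and validation slides alone.

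Most probes past the threshold in both lines fell. Of 2473 Huh7 calls tested in both, 73 passed in THP1 when adjusted over those calls alone, all with the same sign, 63 down and 10 up. They cover 65 genes, among them SLC39A1 (-1.54 in Huh7 and -0.59 in THP1), the lysosomal protein LAMP1 (-0.74 and -0.46), the kinase PDPK1 (-0.82 and -0.47) and the cyclin CCND1 (0.41 and 0.33), which were picked after their values were seen. Without the 2 dim arrays 131 passed, 106 down and 25 up, 127 of them with the same sign. The same 2 control siRNAs served both lines, so an effect of a control could also appear in both. Among the 10 rises are FXR1 and PIP4K2A, which differed between the controls in Huh7. There FXR1 read 0.16 against NC1 and PIP4K2A 0.19 against NC2. How many of the 73 passed against each control singly was not counted. Of the Huh7 falls 87% were below 0 in THP1, against 63.5% of probes not called in Huh7, and of the rises 52.3% were above 0, against 36.5%. Without the dim arrays, which lower the THP1 values, the falls stood at 80.4% against 47.3% and the rises at 73.3% against 52.7%.

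**Figure D4:**
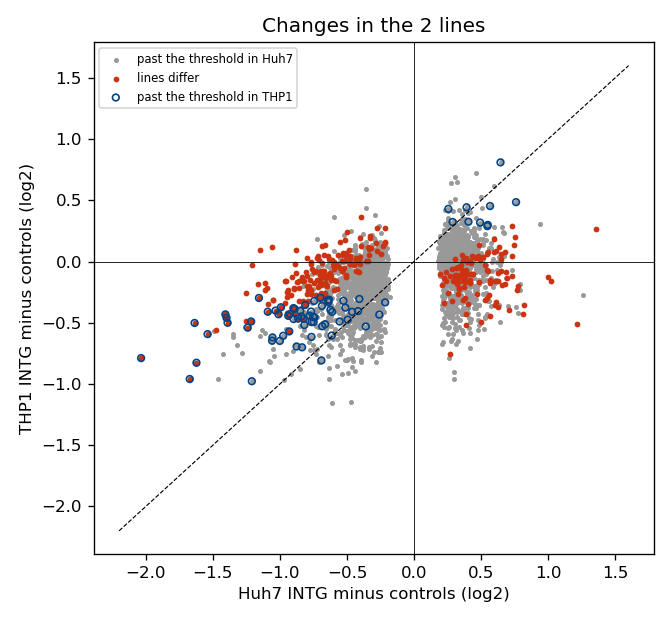
INTG minus controls (log2) in Huh7 (horizontal) and THP1 (vertical) for the 2473 probes past the threshold in Huh7. Red points are probes whose effect differs between lines, blue rings the 73 past the threshold in THP1 among these calls, and the dashed line marks equal change.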

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

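The tests of array brightness, slides, the dim arrays and the PHF19 probes were chosen after the results they bear on had been seen, as were the list counts with the controls kept apart.

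Of 110 sets of 4 experiments, 9 held 1 value far from the other 3, where chance gives about 5.5. In Huh7 these were a PHF19 probe in experiment 3 (-0.66, others -0.81 to -0.79), MT1E in experiment 2 (-1, others -0.40 to -0.33) and the INTG mean signal in experiment 1 (323.9, others 257.6 to 267.8). In THP1 all 6 lay in experiment 4, that of the dim INTG arrays: a PHF19 probe (-0.70), FDPS (0.44), KPNA3 (-1.84), LFNG (-1.31), IVNS1ABP (-1.77) and NT5E (-0.92).

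The INTG effect differed between the lines at 300 probes. The named differences, Huh7 minus THP1, were LFNG 1.72, IVNS1ABP 1.24, NT5E 1.18, PTGER4 1.13, SPRY4 1.10, PNKD -1.25 (0.30 with its other probe, adjusted p = 0.503), MBNL3 -1.24, AMMECR1 -1.19, SEH1L -1.17 and SSR1 -1.14. Without the 2 dim arrays LFNG read 1.45, NT5E 0.93 and IVNS1ABP 0.79, all still past the threshold.

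For the Huh7 response 1 of 81 assignments of the label within experiments, the real one, gave 2894 probes with pooled controls. That is the smallest share 81 assignments allow, so other labels rarely give as many. The highest other gave 37, and among 100 drawn splits that ignore the experiments the highest other gave 45. All of these leave real INTG means among the controls, so 37 and 45 are not counts with no effect present. Dimmer INTG arrays would not predict the response in experiment 1, where brightness was equal: 94.7% of the 2006 calls from experiments 2 to 4 kept their sign there, against 67.8% of other probes, though with a slope of 0.63. A brightness covariate left 532 calls, with the median change at 0.324 against 0.359 and the median SE at 0.116 against 0.0788, so larger errors more than smaller changes ended the calls. Of the discovery calls 94.5% kept their sign on the other slide, against 68.1% of all probes, but each slide held all 3 siRNAs, so this share does not test a slide difference.

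For the smaller number of THP1 changes the dim arrays are opposed as the whole cause, since without experiment 4 THP1 gave 19 probes and Huh7 1766. Over probes called in Huh7, the slope of THP1 on Huh7 changes was at most 0.336 in experiments 1 to 3. It was 0.311 in experiment 4, so the slope does not set the dim arrays apart. For the 0 calls of the validation phase (limma, 900 at an unadjusted p under 0.05) they stay open: experiment 4 correlated with Huh7 at 0.181, or 0.683 times the lowest of the others. That lowest value, 0.265 in experiment 3, came from arrays of ordinary brightness and lay far under 0.618 and 0.672 in experiments 1 and 2, so the dim arrays may be only part of it. A weaker response of the THP1 line, which the design names, was not tested apart from transfection efficiency.

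PHF19 probe 1 in Huh7, the one that did not pass, differed from the mean of the others by 0.70 (interval 0.47 to 0.94, limma unadjusted p = 4.06e-05), and its control level lay 1.17 above the dimmest detected probes.

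For the other counts, splits of the samples gave the following. INTG against both controls in Huh7 gave 1556 probes, as many in 1 of 100 draws, and the highest other draw gave 1357. For this count, in both lines, a draw could keep every real INTG array and exchange only the 2 controls in some experiments. Which kind of draw gave 1357 was not recorded, so it does not show what wrong INTG labels would give. For NC2 against NC1, which is paired within experiments, the 8 splits that part every pair are too few to reach a share under 0.05 (66 against 0 in Huh7, and 0 against 0 in THP1). All 35 splits of the control means, most of which ignore the pairing, gave 66 in 1 of them in Huh7, with 0 as the highest other. In THP1 INTG gave 18 with pooled controls, reached in 1 of 81 assignments (highest other 0) and in 2 of 100 splits that ignore the experiments. There the other split gave 634 and holds both controls of experiment 4, which sets them against the dim arrays. INTG against both controls in THP1 gave 1 probe, reached in 2 of 100 draws with 1 as the highest other. NC2 against NC1 there gave 0 (limma, 237 at an unadjusted p under 0.05 where 676 are expected), as all 35 splits did.

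The difference between lines gave 293 with pooled controls, reached in 3 of 100 draws, and the highest other gave 608. Both other draws that reached it kept the real INTG arrays in all 4 Huh7 experiments, so they set the Huh7 response against a THP1 mix of labels. For the gene lists chance cannot be excluded. In Huh7 33 of 81 assignments gave at least the 2 lists of the pooled fit (highest other 6), and 8 of 81 gave at least 4 in the planned fit (highest other 6). In THP1 42 and 44 of 81 gave at least 1 list (highest other 6 in each).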

How the results depend on the processing

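Of 220 values of the main results under 19 alternatives, 3 of them chosen after seeing the data, 120 stayed on their side or within 1.5 times. Of 1684 values of named genes, 1382 kept direction and side, 234 kept direction and no longer passed, 47 newly passed and 21 changed sign. C5 stayed positive and uncalled under every alternative run in both lines, at 0.05 to 0.16 in Huh7 and 0.01 to 0.08 in THP1 with 1 experiment left out. The cause of the shifts below was not tested unless fewer samples or probes enter. TRAF1, under detection on all arrays, has no value here. Repeated calls were not computed with the slide as block, with the covariate or with experiments left out, nor the line difference with the covariate. The seed-match test was not run.

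With no replicate block Huh7 gave 333 probes against the controls, 142 against both, 0 between controls, 1 list and 170 repeated discovery calls, THP1 gave 0, 0, 2 lists and 0 repeated, and 1 probe differed between lines. The 333 were all among the 3089. With the slide as the only block Huh7 gave 1132, 469, 12 and 1 list, THP1 0, 0 and 2 lists, and the lines differed at 58. With wells kept as separate arrays and the experiment as replicate block, which counts wells as independent, Huh7 gave 2615 against both controls, 405 between controls and 2004 repeated, THP1 547, 123 and 395 repeated, and the lines 1347.

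Pooled controls gave 2 lists in Huh7, and 18 probes and 103 repeated calls in THP1. No background correction gave 187 between controls in Huh7, and 36, 2 and 110 repeated in THP1. The authors' value table gave 436 repeated calls in Huh7 and 0 in THP1. With its floor at 1 in place of the offset it gave 24 between controls and 0 repeated calls in Huh7, and 1 probe, 0 against both and 0 repeated in THP1. So the number of repeated calls depends on how those values are logged. Whether fewer discovery calls or fewer repeats of them gave the lower number was not recorded. No detection filter gave 528 repeated in Huh7, and 3 and 0 in THP1. Detection on all 24 arrays gave 164 between controls in Huh7, 139, 50, 0 lists and 97 repeated in THP1, and 508 between lines. Array weights gave 237 between controls and 489 repeated in Huh7, 259, 80 and 26 repeated in THP1, and 649 between lines.

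The discovery slide alone gave 1217, 382, 0 and 2 lists in Huh7, 282, 66 and 0 lists in THP1, and 46 between lines. The validation slide alone gave 817, 288 and 0 in Huh7, 0 and 0 in THP1, and 0 between lines. Without the dim INTG arrays of experiment 4, THP1 gave 36, 8 and 0 lists, and 523 probes differed between lines. With array brightness as a covariate Huh7 gave 532, 206 and 14, and THP1 30.

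Leaving out 1 experiment gave 1766 to 2492 probes in Huh7 against the controls, 715 to 1061 against both, 3 to 12 between controls and 2 to 5 lists. THP1 gave 0 to 19 (19 without experiment 4), 0 against both, 0 between controls and 0 to 1 list. Between lines it gave 23 to 277.

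Sign changes were among values that did not pass before or after. In Huh7 PHF19 probe 1 read 0.004 with array weights, -0.213 to 0.028 with 1 experiment left out and 0.135 with the brightness covariate, STOM -0.057 on the discovery slide and PSMD5 0.047 with the covariate. In THP1 PHF19 probe 1 read 0.151 with weights, 0.162 on the discovery slide, -0.125 to 0.185 with 1 experiment left out, 0.185 without the dim arrays and 0.168 with the covariate, and PHF19 probe 2 0.011 on the validation slide. THP1 PSMD5 read -0.03, -0.068, -0.035 to 0.153, -0.035 and -0.029 and STOM -0.099, -0.107, -0.086 to 0.087, -0.086 and -0.072 in the same order of settings.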

Other observations

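Further genes that changed in Huh7, named after their values were seen, belong to lists that camera did not call. Among immediate early genes and feedback regulators DUSP5 (0.79), SPRY4 (0.71), SPRY2 (0.61) and DUSP6 (0.56) rose, while FOSB (-0.88), EGR1 (-0.40) and JUN (-0.23) fell. The list has 5 rises and 4 falls among 19 genes, and camera did not call it (adjusted p = 0.446). Among genes of the amino acid response SLC7A5 (-0.86), WARS1 (-0.63), SLC7A1 (-0.57) and TRIB3 (-0.51) fell, and NUPR1 (0.54) and MTHFD2 (0.43) rose, with 6 falls and 3 rises among 26 (adjusted p = 0.446).

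Among complement genes MBL2 (0.84), MASP1 (0.43), CFB (0.29) and C1S (0.24) rose, 4 of 16, and 0 fell (camera adjusted p = 0.446). Among TNF receptor signalling components TAB1 fell by 1.05, with CHUK (-0.37) and FADD (-0.32), while TANK (0.37) and MAP3K7 (0.25) rose (camera adjusted p = 0.446). Of 17 genes of gluconeogenesis, the urea cycle and hepatocyte factors 4 fell, CEBPA (-0.62), CPS1 (-0.59), ONECUT1 (-0.47) and FOXA3 (-0.36), 1 rose, TAT (0.53), and 12 did not pass (camera adjusted p = 0.446).

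Of the 73 probes past the threshold in both lines 86.3% fell, and of the 131 past it without the dim THP1 arrays 80.9% fell. A candidate explanation is silencing of transcripts that partly match the siRNA. With 1 siRNA against the target, no probe for the targeted transcript and no transcript sequences, this cannot be told apart from an effect of losing that transcript.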
